A study of Homo sapiens with 22 samples.

How the data were processed

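The series holds 22 Illumina HT-12 v4 expression arrays of primary human dermal fibroblasts. Per the labels, cells were kept without serum for 24 h and then left untreated (4 arrays, lettered a to d), given 10 µg/ml of poly(I:C), a synthetic double-stranded RNA, for 2 h (3 arrays) or 24 h (3 arrays), given 100 U/ml of interferon-beta (IFN-beta) for 24 h (3 arrays), infected for 48 h at a multiplicity of infection of 50 with adenovirus carrying the transcription factor EGR3 (Ad-EGR3, 2 arrays) or green fluorescent protein (Ad-GFP, 2 arrays), or given for 24 h the chaperone HSP60 (2 arrays), the chromatin protein HMGB1 (2 arrays) or the synthetic triterpenoid CDDO (1 array). The labels give no dose for HSP60, HMGB1 or CDDO and no time for the untreated arrays. Comparisons with the untreated arrays therefore cannot part a treatment from time in culture. The labels do not say whether replicates were separate cultures or donors, so the p values measure only the spread between these samples, which may be technical. Arrays lettered a to d, or numbered 4 and 5 in the HSP60, HMGB1 and CDDO groups, are called by their group and that letter or number.

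The deposited table of unprocessed values holds a linear fluorescence intensity for each of 47323 probes on each array, per the labels exported with the Illumina software. Its values were neither background-subtracted nor scaled between arrays: the lowest intensity of an array lay between 65.9 and 82.5 and the mean intensity between 306 and 650. The same deposited table gives a detection p value for each probe and array, the share of negative control probes at or above its signal, and 38.8 to 44.4% of probes were detected on each array. The authors' own normalised table is on a log2 scale. Per the labels its values were variance-stabilised and quantile-normalised with lumi, and all arrays had the same median of 6.80. The software versions were not stated. The number of arrays and the signal over background limit the precision.

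The comparisons started from the unprocessed intensities. Background was corrected by the normexp model of limma with its parameters taken from the detection p values and an offset of 16, followed by quantile normalisation and log2. Probes with a detection p under 0.05 on at least 2 arrays were kept (28289 probes, of which 19918 had a gene symbol). Each gene was represented by its probe with the highest mean over the 22 arrays, which left 14457 genes. Probes of 1 symbol only were used, and 144 sex-linked probes were removed. Among 118 calls of named genes with several detected probes, a gene counted once in each comparison that called it, all probes moved in the same direction in 107. The exceptions were EGR3 and ZMAT3, each in more than 1 comparison, and HSPD1, CXCL16, SEPTIN4, S100A4, FGFR3 and MCL1.

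All 22 arrays entered 1 fit in limma with a mean per group and no covariate. The spread of each gene was pooled over the groups, so groups of 2 arrays were assumed to vary like the others, and the CDDO array alone added nothing to the spread. Each comparison used limma's moderated two-sided test with Benjamini-Hochberg adjustment over the 14457 genes, and a gene was called at an adjusted p under 0.05. In every comparison 723 genes would have an unadjusted p under 0.05 by chance alone. Errors given with log2 fold changes are standard errors (SE) of that fit, and those given with levels are standard deviations (SD). Where no array of one group detected a gene, the fold is a bound ("at least"), taken against the background level. The 10 tested comparisons were poly(I:C) 2 h, poly(I:C) 24 h, IFN-beta, Ad-GFP, HSP60 and HMGB1 against control, poly(I:C) 24 h against 2 h, poly(I:C) 24 h against IFN-beta, Ad-EGR3 against Ad-GFP, and HSP60 against HMGB1. CDDO had 1 array and no test: genes were counted that lay at least 1 log2 unit from the mean of the controls and outside the range of the 4 controls, and each control was counted by the same rule against the other 3.

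A set of 22 gene lists was fixed in advance: interferon-stimulated genes, RNA sensing and interferon production, MHC class I antigen presentation, chemokines and cytokines, NF-kB feedback and adhesion genes, extracellular matrix, TGF-beta response and myofibroblast genes, matrix proteases and inhibitors, cell cycle, sterol synthesis, NRF2 targets, p53 targets, immediate early and EGR family, unfolded protein response, heat shock proteins, cell death and inflammasome, fibroblast identity, and markers of keratinocytes, endothelial cells, leukocytes, melanocytes, and smooth muscle and pericytes. For each list the members called among all genes tested were counted, as were those passing when the p values were adjusted over the list alone. Lists were tested against all other genes with camera in limma, with a preset inter-gene correlation of 0.01 and again with an estimated correlation, adjusted over the lists of a comparison. A list with 2 measured members (melanocytes) was counted and not tested. For CDDO, the median of each list was set against 10000 random lists of genes of like level. Genes named in the text are the 10 highest and 10 lowest log2 fold changes among called genes with every array of one group on one side of every array of the other, up to 4 members of a described list with the smallest adjusted p, and a short fixed set (EGR3, EGR1, EGR2, NAB2, IFNB1, COL1A1, COL1A2, ACTA2, TLR3, HSPD1, HMGB1, HMOX1, NQO1). Genes with placeholder symbols were not named. These choices, the comparisons and the alternatives were fixed before the data were examined, except for the alternatives and tests that the closing section names as chosen later.

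The procedure was tested on simulated data with the same group sizes. Added changes of 1 log2 unit were recovered in 26 to 60% of cases and changes of 2 log2 units in 82 to 98%, depending on the comparison, with 2.13 to 6.09 false calls per 100 calls. The simulated errors were independent between genes, with 1 spread per gene for all groups. The real groups spread unequally (median SD 0.354 for Ad-EGR3, 0.309 for Ad-GFP and 0.19 for the controls), so these rates may not hold for them. Comparisons that share the 4 controls were set against simulations of unchanged groups that share them too.

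Alternatives were the authors' values, no background correction, median scaling in place of quantile normalisation, no filter or a stricter filter on detection, the mean of all probes of a gene, only the 2 groups compared in the fit, the replicate letter as a block, array weights, moderation with trend and robust options, a minimum log2 fold change of 1, and leaving out each array in turn. Replicate letters were checked for pairing by correlating, across genes, the deviations of same-lettered samples from their group means. For poly(I:C) at 2 h and 24 h this correlation was 0.16 to 0.266 over the 3 letters, and each sample correlated best with its own letter. The letters therefore paired these samples by the check alone, since the labels do not say what a letter marks. R 4.3.3 with limma 3.58.1 and Python 3.11.15 with numpy 2.4.6, pandas 2.3.3 and matplotlib 3.10.9 were used.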

Results

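After 2 h of poly(I:C), a synthetic double-stranded RNA, the transcript of interferon-beta itself rose most: IFNB1 was at a log2 signal of 9.69 ± 0.23 (SD, n = 3) against 4.40 ± 0.16 (SD, n = 4) in untreated fibroblasts. No untreated array detected it, and it was at least 24.9-fold higher (adjusted p = 4.59e-12). PMAIP1, which encodes the pro-apoptotic protein NOXA, rose by 3.15 log2 units (SE 0.39, adjusted p = 0.000857). TNFAIP3, the ubiquitin-editing enzyme A20 that dampens NF-kB signalling, rose by 3.55 (SE 0.71, adjusted p = 0.0434). IFIT2, an interferon-stimulated antiviral gene, rose by 3.07 (SE 0.60, adjusted p = 0.0384) and OASL, a relative of the antiviral oligoadenylate synthetases, by 1.94 (SE 0.39, adjusted p = 0.0442). NOCT, nocturnin, a protein of the circadian rhythm, rose by 2.14 (SE 0.28), the kinase gene NUAK2 by 2.01 (SE 0.24) and ANKRD36BP1, a pseudogene, by 1.96 (SE 0.24). Further increases were those of BCL3, an atypical inhibitor-of-kappa-B protein, by 1.75 (SE 0.36) and ZFP36, which promotes the decay of cytokine mRNAs, by 1.48 (SE 0.25). The strongest decreases were smaller: NPIPA1 fell by 1.53 (SE 0.26). MAPK8IP3, a scaffold of the JNK pathway, fell by 1.52 (SE 0.22), GOLGA8B by 1.43 (SE 0.21) and PCTP, a phosphatidylcholine transfer protein, by 1.23 (SE 0.23). The pseudogenes AHSA2P, SMG1P1 and FAM133CP fell by 1.23 (SE 0.26), by 1.20 (SE 0.20) and by 1.18 (SE 0.23). TARDBP, the RNA-binding protein TDP-43, fell by 1.15 (SE 0.21), AKAP10, an anchor of protein kinase A, fell by 1.12 (SE 0.21) and NBPF14 fell by 1.07 (SE 0.19). By the rule that chose these 20 genes, every array at 2 h lay on one side of the 4 controls, which is no separate support.

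Of the 19 measured genes of NF-kB feedback and adhesion, 2 rose at 2 h (TNFAIP3 and BCL3) and none fell, and 4 rose when adjusted over the list alone. The list was called higher by camera (adjusted p = 0.00407), which was lost at adjusted p = 0.844 with an estimated correlation. Of the 36 interferon-stimulated genes, 2 rose (IFIT2 and OASL), both also when adjusted over the list alone, and the list was not called (adjusted p = 0.788). Of 16 genes of RNA sensing and interferon production 1 rose (IFNB1; 2 adjusted over the list alone), and of 17 genes of cell death and the inflammasome 1 rose (PMAIP1). None of the 30 chemokines and cytokines passed: IL6 was at a log2 fold change of 2.54 (SE 1.19, adjusted p = 0.432) and CXCL2, a neutrophil chemokine, at 2.45 (SE 1.14, adjusted p = 0.426). None of the 23 immediate early and EGR family genes passed either, although camera called the list higher (adjusted p = 0.0169; adjusted p = 0.844 with an estimated correlation). JUNB was at 1.30 (SE 0.39, adjusted p = 0.188), EGR1 at 0.29 (SE 0.34, adjusted p = 0.813) and EGR3 at 0.15 (SE 0.34, adjusted p = 0.931). Camera also called MHC class I antigen presentation (adjusted p = 0.0169), extracellular matrix (adjusted p = 0.018) and matrix proteases and inhibitors (adjusted p = 0.019) lower, and the cell cycle list higher (adjusted p = 0.0436), with no member passing among all genes tested. With an estimated correlation these became adjusted p = 0.844, 0.844, 0.187 and 0.952, and with median scaling they missed as well (adjusted p = 0.127, 0.489, 0.127 and 0.143). MMP14 and MMP2, a membrane-bound and a secreted metalloprotease, passed when adjusted over the protease list alone.

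In all, 45 genes were called at 2 h, 13 higher and 32 lower, and 1617 had an unadjusted p under 0.05. The count depended on single arrays: it was 14, 10, 9 and 13 without control a, b, c and d, and 23, 7 and 6 without poly(I:C) 2 h a, b and c. IFNB1, PMAIP1, NOCT, NUAK2 and ANKRD36BP1 passed in each of these. GOLGA8B missed only without poly(I:C) 2 h c (adjusted p = 0.0706), MAPK8IP3 only without poly(I:C) 2 h b (adjusted p = 0.0554). TNFAIP3, IFIT2 and OASL missed in all but the fit without control a (adjusted p up to 0.216 for TNFAIP3, 0.213 for IFIT2 and 0.214 for OASL). BCL3, AHSA2P, AKAP10 and TARDBP missed without any 1 of the 7 arrays (adjusted p up to 0.287, 0.318, 0.145 and 0.135), and NPIPA1, PCTP, FAM133CP, SMG1P1, NBPF14 and ZFP36 without 4 to 6 of them (adjusted p up to 0.162, 0.213, 0.251, 0.117, 0.192 and 0.135). The split into higher and lower was 6 and 5 of 11 calls with median scaling in place of quantile normalisation.

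At 24 h of poly(I:C), the fibroblasts carried a broad antiviral and chemokine profile. CXCL10, a chemokine for T cells, rose by 8.86 log2 units (SE 1.09, n = 3 against 4, adjusted p = 4.55e-06), CCL8 by 8.35 (SE 0.77), CCL5 by 7.81 (SE 0.37, adjusted p = 3.19e-11) and OASL by 8.48 (SE 0.39). IDO1, which degrades tryptophan, was at least 321-fold higher (adjusted p = 1.27e-12), TNFSF10, the death ligand TRAIL, at least 222-fold. CD38, an enzyme that consumes NAD, was at least 105-fold and CXCL9 at least 48.2-fold higher. IFI27 rose by 7.89 (SE 1.40), IL18BP, a decoy for interleukin 18, by 7.25 (SE 0.52) and BST2, which tethers budding virus (tetherin), by 7.20 (SE 0.68). For CXCL10, IFI27 and BST2, control a stood far above the other controls, so the size of the rise depends in part on that array. Among the strongest decreases were STMN2, a regulator of microtubules (fell by 3.93, SE 0.69), NT5DC2 (at least 10.6-fold lower), the RNA gene DANCR (fell by 3.86, SE 0.25) and MTURN (fell by 3.69, SE 0.23). They also included GSTM3, a glutathione transferase (fell by 3.64, SE 0.19), GALNT11, a glycosyltransferase (fell by 3.53, SE 0.32) and PSAT1, an enzyme of serine synthesis (fell by 3.49, SE 0.21). RAB40B fell by 3.47 (SE 0.17), FEZ1 fell by 3.40 (SE 0.17) and the cation channel gene TRPC6 was at least 8.58-fold lower.

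Of 36 interferon-stimulated genes, 35 rose and none fell (36 adjusted over the list alone), among them ISG20, an exonuclease (5.45, SE 0.27) and SAMD9 (4.45, SE 0.41). The exception, IFI6, was chosen after its values were seen, at 1.65 (adjusted p = 0.0809). The list was called higher (adjusted p = 6.18e-23), with adjusted p = 0.209 with an estimated correlation. Of 16 genes of RNA sensing and interferon production, 13 rose (13 adjusted over the list alone). TLR3, the endosomal sensor of double-stranded RNA, was at 4.46 (SE 0.23, adjusted p = 9.45e-11), RIGI, a cytosolic RNA sensor, at 5.49 (SE 0.56), and IFNB1 was still at least 8.47-fold higher. The call (adjusted p = 7.69e-11) held with an estimated correlation (adjusted p = 0.0357). Of 16 genes of MHC class I antigen presentation, 15 rose, on either adjustment, such as HLA-F (3.33, SE 0.28), HLA-C (2.80, SE 0.22) and the immunoproteasome subunit gene PSMB9 (3.95, SE 0.38). The list was at adjusted p = 3.37e-13 and adjusted p = 0.0357 with an estimated correlation. Of 17 genes of cell death and the inflammasome 14 rose (15 adjusted over the list alone). AIM2, a sensor of cytosolic DNA, was at 4.95 (SE 0.25), MLKL, the executor of necroptosis, at 4.36 (SE 0.37) and the kinase gene RIPK2 at 2.79 (SE 0.26), and the list was at adjusted p = 2.61e-09 and adjusted p = 0.0224 with an estimated correlation. Chemokines and cytokines rose in 21 of 30 (24 rose and 1 fell adjusted over the list alone), at adjusted p = 3.04e-13 and adjusted p = 0.18 with an estimated correlation. NF-kB feedback and adhesion genes rose in 15 of 19 (16 adjusted over the list alone). TNFAIP3 was at 4.53 (SE 0.71) and TNFAIP6, a hyaluronan-binding protein, at 4.25 (SE 0.68), and the list was at adjusted p = 1.16e-08 and adjusted p = 0.256 with an estimated correlation.

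**Figure D1:**
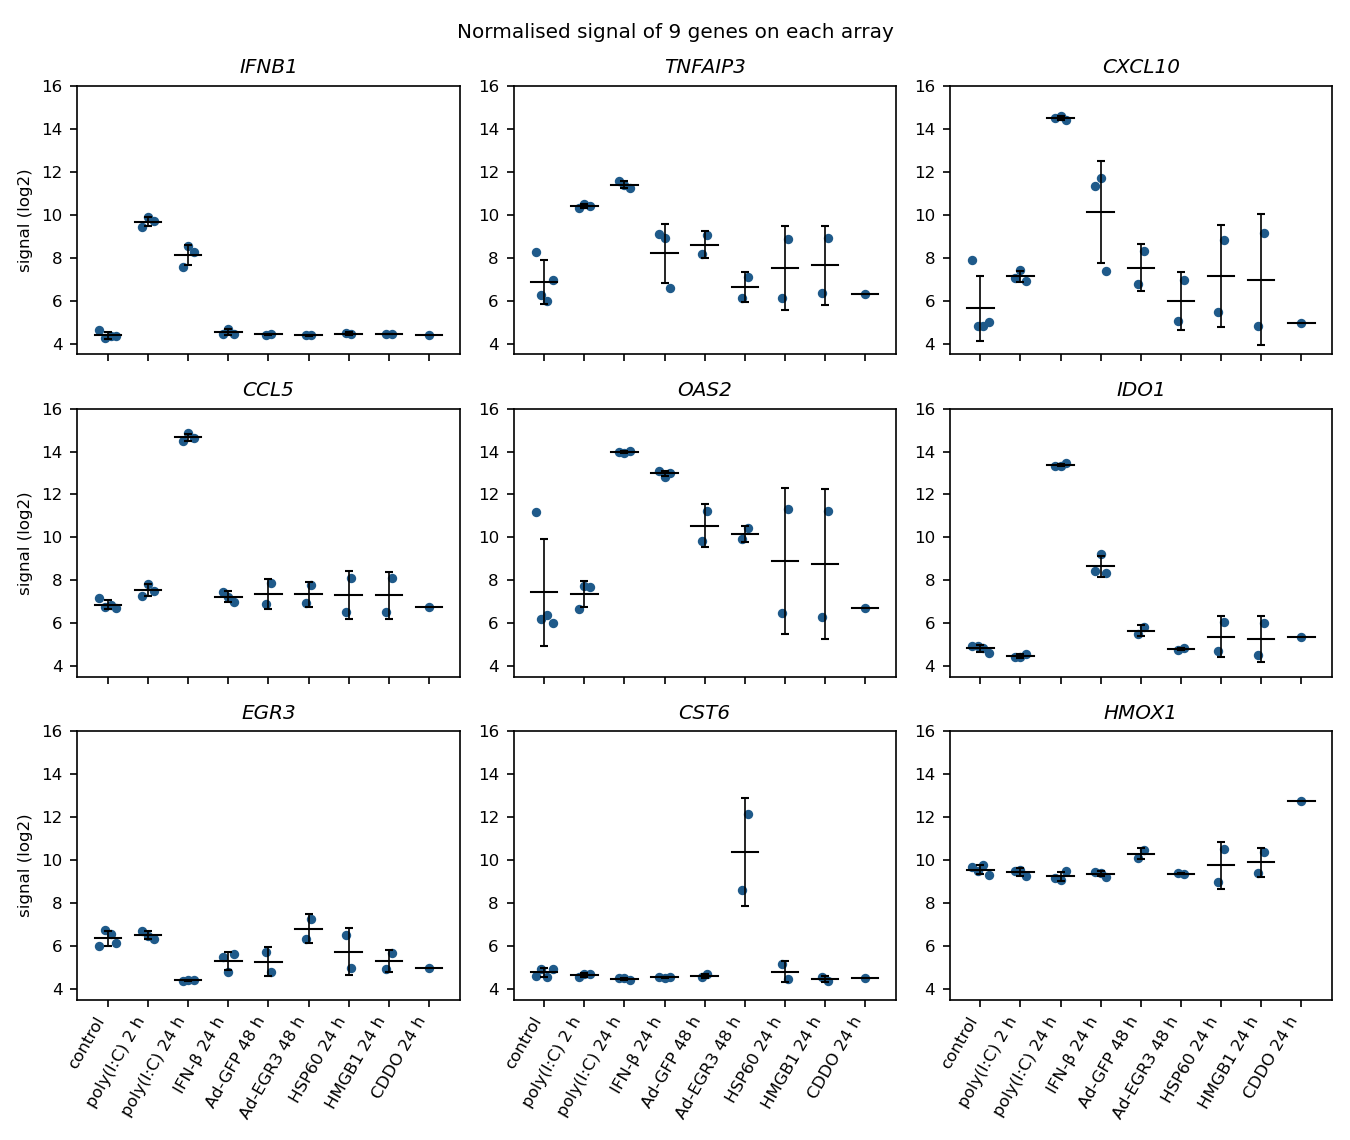
Log2 signal (background-corrected, quantile-normalised) of 9 genes, 1 panel each, with the 9 groups of arrays along the horizontal axis; points are arrays, the line is the group mean and bars are the SD of groups with 2 or more arrays. IFNB1 stood at 9.69 after 2 h of poly(I:C) against 4.40 in the 4 controls, while CXCL10, CCL5 and IDO1 were highest in the poly(I:C) 24 h group.

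Genes of the connective tissue programme went both ways at 24 h of poly(I:C). Of 38 measured extracellular matrix genes, 1 rose (COL4A1, a basement membrane collagen, 1.11, SE 0.20) and 8 fell, the same counts as adjusted over the list alone. Those that fell included FBN2, a microfibril protein (fell by 2.52, SE 0.38), COL14A1 (fell by 1.74, SE 0.30) and VCAN, the proteoglycan versican (fell by 1.66, SE 0.19). The type I collagen genes did not pass, COL1A1 at -0.22 (SE 0.14, adjusted p = 0.249) and COL1A2 at -0.07 (SE 0.23, adjusted p = 0.848). Of 33 genes of the TGF-beta response and myofibroblasts, 3 rose and 11 fell (3 and 12 adjusted over the list alone). EDN1, the vasoconstrictor endothelin, rose by 2.92 (SE 0.51), PMEPA1, a feedback inhibitor of TGF-beta signalling, fell by 2.59 (SE 0.33) and TPM1, a tropomyosin, fell by 1.22 (SE 0.19). ACTA2, smooth muscle actin, was at -0.24 (SE 0.21, adjusted p = 0.422). Matrix proteases and inhibitors split into 5 higher and 4 lower of 18 (7 and 4 adjusted over the list alone). The collagenase MMP1 was at 2.44 (SE 0.45) and the aggrecanases ADAMTS1 and ADAMTS5 at -1.92 (SE 0.20) and -3.06 (SE 0.66). Of 12 fibroblast identity genes 3 rose and 3 fell (3 and 4 adjusted over the list alone). TWIST2, a transcription factor, was at 2.04 (SE 0.23) and FAP, a membrane protease, at -2.12 (SE 0.16). Camera called none of these 4 lists (adjusted p = 0.41, 0.178, 0.897 and 0.901).

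The immediate early and EGR family list had 10 genes that rose and 3 that fell of 23 (11 and 4 adjusted over the list alone). ATF3, a stress-induced transcription factor, was at 3.45 (SE 0.51) and DUSP5, a MAP kinase phosphatase, at 2.48 (SE 0.32), and the list was at adjusted p = 0.0475, adjusted p = 0.635 with an estimated correlation and adjusted p = 0.0677 with no filter on detection. EGR3 itself fell, at least 2.35-fold (adjusted p = 0.000177) by the probe that represented it, while its other detected probe was at 0.215. NAB2, a corepressor of EGR proteins, fell by 1.01 (SE 0.15), and EGR1 did not pass at -0.86 (SE 0.34, adjusted p = 0.0526). None of the remaining lists was called at 24 h. Cell cycle genes fell in 3 of 34, on either adjustment (MCM6, a replication helicase subunit, CCNB2, a mitotic cyclin, and TYMS, thymidylate synthase, at -1.38, -1.46 and -0.69), at adjusted p = 0.104. Sterol synthesis had 2 higher and 3 lower of 18 (TM7SF2 at 1.90 and ACAT2 at -0.91), adjusted p = 0.897. NRF2 targets had 3 higher and 8 lower of 22 (AKR1C2 at 1.94 and TKT, transketolase, at -1.65), adjusted p = 0.454. The p53 targets had 2 higher and 7 lower of 18 (the death receptor FAS at 2.47 and ZMAT3 at -1.70), adjusted p = 0.383. The unfolded protein response list had 3 higher and 3 lower of 16 (XBP1 at 0.73 and ASNS, asparagine synthetase, at -2.46), adjusted p = 0.897. Heat shock proteins had 4 higher and 2 lower of 13 (HSPA1B at 1.39 and DNAJB1 at -0.84), adjusted p = 0.41. For markers of other cell types, 1 of 4 keratinocyte genes rose and 1 fell (DSP, desmoplakin, at 1.62 and KRT10 at -2.38; DSP missed without poly(I:C) 24 h b, adjusted p = 0.0508), adjusted p = 0.897. Of the endothelial genes 2 of 5 rose (TEK at 2.37, and KDR, at least 1.5-fold), adjusted p = 0.104. Of smooth muscle and pericyte genes 2 of 9 rose and 3 fell (MYH11, smooth muscle myosin, at 3.96 and NOTCH3 at -1.34), adjusted p = 0.897. None of 7 leukocyte (adjusted p = 0.901) or 2 melanocyte genes passed. Median and mean of the list differed in sign for the unfolded protein response (0.389 and -0.072), fibroblast identity (-0.14 and 0.055), keratinocyte (0.118 and -0.131), leukocyte (-0.033 and 0.104) and smooth muscle lists (-0.177 and 0.241).

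In all, 5100 genes were called at 24 h of poly(I:C), 2236 higher and 2864 lower, of which 1305 and 1430 had a log2 fold change of at least 1 in size. With median scaling in place of quantile normalisation the median log2 fold change of all genes was -0.13 against -0.06, so changes near that size have no firm direction.

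IFN-beta for 24 h raised antiviral genes. IFI27 rose by 7.12 log2 units (SE 1.40, n = 3 against 4, adjusted p = 0.00707), BST2 by 5.91 (SE 0.68, adjusted p = 5.12e-05), OAS1, which activates RNase L, by 5.90 (SE 1.07) and OASL by 5.34 (SE 0.39, adjusted p = 1.09e-06). HERC5, the ligase that attaches ISG15, rose by 5.39 (SE 1.06), RSAD2 (viperin) by 5.19 (SE 0.96), MX2, an antiviral GTPase, by 5.19 (SE 0.95) and IL18BP by 4.99 (SE 0.52). IFI44L rose by 5.99 (SE 1.32) and OAS2 by 5.52 (SE 1.21), both at adjusted p = 0.0157. For these genes other than OASL and IL18BP, control a stood far above the other controls, so the size of the rise depends in part on that array. The strongest decreases were HSD17B14, a steroid dehydrogenase (fell by 2.96, SE 0.51), HNRNPA1P10, a pseudogene (fell by 2.55, SE 0.29), DANCR (fell by 2.12, SE 0.25), MTURN (fell by 1.98, SE 0.23) and ATPSCKMT, a lysine methyltransferase (fell by 1.62, SE 0.24). They were followed by NT5DC2 (fell by 1.58, SE 0.24), TXNDC12, a thioredoxin-like protein of the endoplasmic reticulum (fell by 1.57, SE 0.25), SNHG9 (fell by 1.36, SE 0.25), UBE4B, a ubiquitin ligase (fell by 1.29, SE 0.26) and FABP3, a fatty acid binding protein (fell by 1.26, SE 0.24). IFNB1 itself was not detected (0.14, SE 0.19, adjusted p = 0.96), and EGR3 did not pass at -1.05 (SE 0.34, adjusted p = 0.167).

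Interferon-stimulated genes rose in 35 of 36 with IFN-beta (36 adjusted over the list alone), and IFI6, named again after its values were seen, was at 2.74 (adjusted p = 0.0523). The call (adjusted p = 3.18e-72) held with an estimated correlation (adjusted p = 0.0163). MHC class I antigen presentation rose in 12 of 16 (14 adjusted over the list alone). HLA-C was at 2.16 (SE 0.22), HLA-B at 2.57 (SE 0.34) and the peptide transporter gene TAP2 at 2.28 (SE 0.33), and the list was at adjusted p = 1.66e-30 and adjusted p = 0.00215 with an estimated correlation. RNA sensing and interferon production rose in 6 of 16 (7 adjusted over the list alone), with TLR3 at 2.67 (SE 0.23) and RIGI at 4.08 (SE 0.56), at adjusted p = 2.44e-12 and adjusted p = 0.0163 with an estimated correlation. In cell death and the inflammasome 3 of 17 rose (4 adjusted over the list alone). They were MLKL at 2.59 (SE 0.37), APOL6 at 1.46 (SE 0.25) and CASP1, the inflammasome caspase, at 1.63 (SE 0.34), with the list at adjusted p = 1.22e-07 and adjusted p = 0.0163 with an estimated correlation. Of the chemokines and cytokines 5 of 30 rose (8 adjusted over the list alone): TNFSF10, at least 16.4-fold, TNFSF13B, the B-cell factor BAFF, at 3.68 (SE 0.43), CXCL16 at 2.53 (SE 0.35), CCL8 at 3.35 (SE 0.77) and CXCL10 at 4.50 (SE 1.09), the last named after its values were seen. The other detected probe of CXCL16 was at -0.044. The chemokine list was called at adjusted p = 1.22e-07, with adjusted p = 0.379 with an estimated correlation. Its mean stood at 1.51 and 1.64 on IFN-beta a and b but at 0.34 on IFN-beta c, below untreated control a (0.85). No NF-kB feedback or adhesion gene and no TGF-beta response gene passed, on either adjustment. Camera called the first list higher (adjusted p = 0.000406; adjusted p = 0.577 with an estimated correlation) and the second lower (adjusted p = 0.0107; adjusted p = 0.379 with an estimated correlation). The mean of the NF-kB list was likewise uneven, at 1.18 and 1.15 on IFN-beta a and b and -0.20 on IFN-beta c, against 0.99 on control a. In fibroblast identity NT5E, an ectonucleotidase, rose by 1.16 (SE 0.23) and FAP fell by 1.08 (SE 0.16).

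In all, 309 genes were called with IFN-beta, 247 higher and 62 lower, and 256 and 19 with median scaling, where the median log2 fold change of all genes was 0.11 against -0.01. The count was 180 without IFN-beta b and 190 without IFN-beta a. Leaving out control b, c or d or IFN-beta a, b or c each ended the calls of IFI44L (adjusted p = 0.0608 to 0.0788) and OAS2 (adjusted p = 0.0616 to 0.0759). CCL8 missed without control b, c or d or IFN-beta a or b (adjusted p = 0.0747 to 0.2). Without IFN-beta b CASP1 (0.0669), UBE4B (0.0589) and NT5E (0.0632) missed, without IFN-beta c CASP1 (0.0509) and without IFN-beta a NT5E (0.056).

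The responses to IFN-beta and to poly(I:C) at 24 h overlapped. Of the 247 genes that rose with IFN-beta, 242 also rose with poly(I:C), and of the 62 that fell, 61 also fell. No gene was called in opposite directions, and independent calls would share 38.2 and 12.3. In 20 simulations of unchanged groups against the same 4 controls, no gene was called in both, which says little because unchanged groups have few calls to share. With separate pairs of controls for each treatment, 95 to 188 genes rose with IFN-beta, and 94 to 184 rose with both. Likewise 10 to 25 fell with IFN-beta, and 8 to 23 with both. DANCR, MTURN and NT5DC2 were among the 10 strongest decreases of each treatment, and OASL, IFI27, BST2 and IL18BP among the 10 strongest increases of each. Across the 14457 genes, which are not independent replicates, the log2 fold changes correlated at r = 0.702, where simulated unchanged groups sharing the controls gave 0.426 (0.385 to 0.453). With separate pairs of controls for each treatment r was 0.634. All 35 interferon-stimulated genes that rose with IFN-beta rose with poly(I:C), as did the 12 MHC class I, 6 RNA sensing, 5 chemokine and 3 cell death genes. A further 15 NF-kB feedback and adhesion genes, 16 chemokines and cytokines, 11 cell death, 7 RNA sensing and 3 MHC class I genes were called with poly(I:C) and not with IFN-beta. The direct comparison of the treatments tests that difference.

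**Figure D2:**
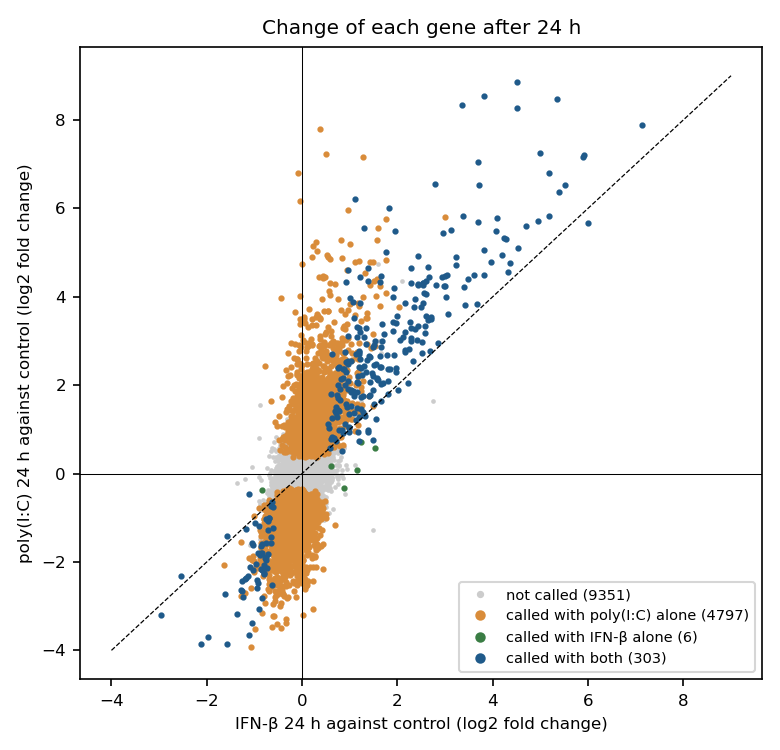
Log2 fold change against control of each of 14457 genes with IFN-beta for 24 h (horizontal axis) and with poly(I:C) for 24 h (vertical axis); each point is a gene, colours mark the test calls and the dashed line is equality. The 303 genes called with both treatments lie in the same direction for both, and 4797 genes were called with poly(I:C) alone and 6 with IFN-beta alone.

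Set directly against IFN-beta at 24 h, poly(I:C) raised several chemokine genes further. CCL5 was higher by 7.43 log2 units (SE 0.39, n = 3 against 3, adjusted p = 4.85e-10), CD38 by 6.74 (SE 0.24), CXCL11 by 5.88 (SE 0.46) and CCL8 by 5.00 (SE 0.82). PLAAT2, a phospholipase, was higher by 5.09 (SE 0.24), TFPI2, a protease inhibitor, by 4.99 (SE 0.97), HAS3, a hyaluronan synthase, by 4.95 (SE 0.35) and SEPTIN4 by 4.93 (SE 0.49). The detected probes of SEPTIN4 ranged from -0.012 to 4.927. IL1RN, the interleukin 1 receptor antagonist, was at least 76.8-fold and CXCL9 at least 48.8-fold higher. Lower with poly(I:C) were ADAMTS5 (-3.28, SE 0.71), PSAT1 (-3.05, SE 0.23), KDELR3, a retrieval receptor of the secretory pathway (-2.95, SE 0.24), FEZ1 (-2.88, SE 0.18) and STMN2 (-2.86, SE 0.73). So were RAB40B (-2.84, SE 0.19), the alcohol dehydrogenase gene ADH1A (-2.75, SE 0.54), ALDH1A3, which makes retinoic acid (at least 7.82-fold), TRPC6 (at least 6.76-fold) and PKD1L2 (at least 3.94-fold).

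Chemokines and cytokines were higher with poly(I:C) than with IFN-beta in 18 of 30 (18 adjusted over the list alone), at adjusted p = 8.86e-12 and adjusted p = 0.295 with an estimated correlation. NF-kB feedback and adhesion genes were higher in 12 of 19 (15 adjusted over the list alone), with the adhesion molecule ICAM1 at 3.13 (SE 0.71) and the adaptor TRAF1 at 2.14 (SE 0.24). The list was at adjusted p = 3.46e-07 and adjusted p = 0.385 with an estimated correlation. Cell death genes were higher in 10 of 17 (11 adjusted over the list alone), AIM2 by 4.42 (SE 0.26), at adjusted p = 3.51e-07 and adjusted p = 0.0572 with an estimated correlation. RNA sensing was higher in 6 of 16 (8 adjusted over the list alone), TLR3 by 1.79 (SE 0.25) and IFNB1 at least 8.59-fold, at adjusted p = 1.21e-06 and adjusted p = 0.242 with an estimated correlation. MHC class I antigen presentation was higher in 10 of 16 (11 adjusted over the list alone), with TAPBP, which loads peptides, at 1.51 (SE 0.33), at adjusted p = 4.76e-05 and adjusted p = 0.314 with an estimated correlation. Immediate early genes were higher in 9 and lower in 1 of 23 (9 and 2 adjusted over the list alone), with DUSP5 at 2.60 (SE 0.34), at adjusted p = 0.00468 and adjusted p = 0.398 with an estimated correlation. Of the interferon-stimulated genes 4 of 36 were higher (3 adjusted over the list alone) and 32 did not pass. OASL was higher by 3.13 (SE 0.42), ISG20 by 2.48 (SE 0.29), SAMD9 by 1.52 (SE 0.44) and SAMD9L by 1.5 (SE 0.48), with the list at adjusted p = 0.00114 and adjusted p = 0.828 with an estimated correlation. Extracellular matrix genes were lower in 11 and higher in 1 of 38, on either adjustment. VCAN was at -1.80 (SE 0.20), COL6A3 at -1.17 (SE 0.22) and COL1A1 at -0.57 (SE 0.15, adjusted p = 0.00995), and the list was at adjusted p = 0.0485, adjusted p = 0.53 with an estimated correlation and adjusted p = 0.245 with median scaling. The proteases MMP1 (3.21, SE 0.48) and ADAMTS1 (-2.13, SE 0.22) moved apart, with 5 higher and 2 lower of 18.

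In all, 3370 genes differed, 1452 higher and 1918 lower with poly(I:C), and 771 and 2748 with median scaling, where the median log2 difference of all genes was -0.23 against -0.04. SAMD9 missed without poly(I:C) 24 h a or b or IFN-beta a or c (adjusted p = 0.0541 to 0.0615), and SAMD9L without poly(I:C) 24 h a, b or c or IFN-beta a or c (adjusted p = 0.0684 to 0.116).

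**Figure D3:**
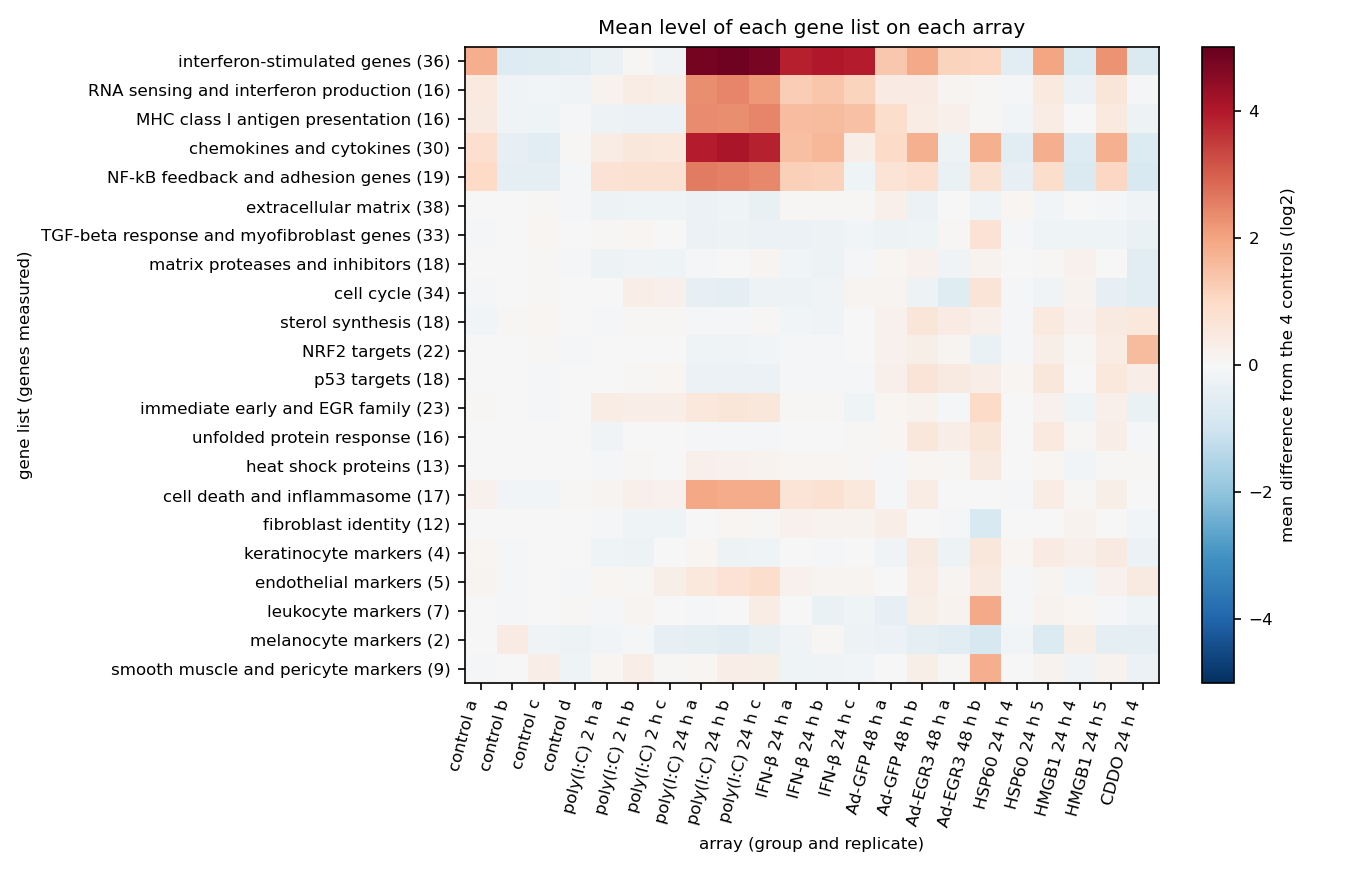
Heat map of the mean log2 signal of each gene list (vertical axis) on each of the 22 arrays (horizontal axis), minus the mean of the 4 controls; colour gives the difference in log2 units. The interferon-stimulated list stood at 4.73 to 4.85 on the poly(I:C) 24 h arrays and at 3.88 to 4.02 on the IFN-beta arrays, and at 1.83 on control a, 1.99 on HSP60 5 and 2.24 on HMGB1 5.

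Between 2 h and 24 h of poly(I:C), IFNB1 fell by 1.56 log2 units (SE 0.20, n = 3 against 3, adjusted p = 7.7e-06), and the antiviral genes that interferon induces rose. OASL rose by a further 6.53 (SE 0.42), IFI27 by 9.05 (SE 1.5), OAS1 by 7.83 (SE 1.14), CXCL10 by 7.37 (SE 1.17), CCL8 by 7.49 (SE 0.82) and IL18BP by 7.19 (SE 0.56). IDO1 was at least 304-fold, BST2 at least 248-fold, TNFSF10 at least 210-fold, RSAD2 at least 169-fold and CD38 at least 99.5-fold higher at 24 h. DANCR fell by 4.21 (SE 0.26), STMN2 by 3.98 (SE 0.73), GSTM3 by 3.92 (SE 0.20) and MTURN by 3.86 (SE 0.25). RAB40B fell by 3.78 (SE 0.19), PSAT1 by 3.76 (SE 0.23), FEZ1 by 3.64 (SE 0.18) and GSTA4, another glutathione transferase, by 3.52 (SE 0.31). NT5DC2 and TRPC6 were at least 14.7-fold and 11.2-fold lower. EGR3 was at least 2.61-fold lower (adjusted p = 0.000173), while its other detected probe was at 0.379. EGR1 was lower by a log2 difference of -1.15 (SE 0.36, adjusted p = 0.0172), which missed without poly(I:C) 2 h a or poly(I:C) 24 h a or b (adjusted p = 0.0504 to 0.0665).

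By list, 35 of 36 interferon-stimulated genes were higher at 24 h than at 2 h, on either adjustment (adjusted p = 4.67e-22; adjusted p = 0.225 with an estimated correlation). So were 15 of 16 MHC class I genes, on either adjustment (adjusted p = 3.48e-14; adjusted p = 0.0279 with an estimated correlation), and 12 of 17 cell death genes (13 adjusted over the list alone; adjusted p = 1.1e-07; adjusted p = 0.0279 with an estimated correlation). Chemokines and cytokines were higher in 20 of 30, on either adjustment (adjusted p = 2.35e-11; adjusted p = 0.225 with an estimated correlation), and NF-kB genes were higher in 12 of 19 (13 adjusted over the list alone; adjusted p = 8.92e-05; adjusted p = 0.566 with an estimated correlation). In RNA sensing 13 of 16 were higher, with TLR3 at 4.40 (SE 0.25), and 1 was lower, IFNB1, on either adjustment (adjusted p = 1.66e-07; adjusted p = 0.119 with an estimated correlation). Cell cycle genes were lower in 7 of 34, on either adjustment, with MCM6 at -1.78 (SE 0.18) and CENPF at -1.11 (SE 0.22) (adjusted p = 0.0131; adjusted p = 0.702 with an estimated correlation). In all, 4933 genes differed, 2192 higher and 2741 lower at 24 h.

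Infection with Ad-EGR3, compared with Ad-GFP at 48 h, raised most strongly several genes that were not detected with the control virus. KISS1R, the kisspeptin receptor, was at least 160-fold higher (adjusted p = 5.81e-06, n = 2 against 2), CST6, a cysteine protease inhibitor, and FGFR3, a fibroblast growth factor receptor, each at least 41-fold. The other detected probe of FGFR3 was at a log2 fold change of -0.267. TMEM145 was at least 24.6-fold, NPAS1, a transcription factor of neurons, at least 23.9-fold, VGF, a neuropeptide precursor, at least 22.8-fold and ARC, a synaptic immediate early gene, at least 20.6-fold higher. HBA2, an alpha globin, rose by 5.67 log2 units (SE 0.79), the neuropeptide gene NPW by 5.13 (SE 0.44) and SLCO2A1, a prostaglandin transporter, by 5.02 (SE 0.49). The strongest decreases were ADH1A (fell by 2.63, SE 0.66), PTX3, a soluble pattern recognition protein (fell by 2.43, SE 0.59), RIPOR3 (fell by 2.33, SE 0.41) and PTGES, a prostaglandin E synthase (fell by 2.32, SE 0.46). SGSH, a lysosomal enzyme (fell by 2.10, SE 0.46), ANGPT1, an angiopoietin (fell by 2.09, SE 0.57), the kinase gene MAP3K12 (fell by 2.04, SE 0.34), SLC9A9 (fell by 1.96, SE 0.47), AKR1C2 (fell by 1.92, SE 0.43) and SREBF1, a regulator of lipid synthesis (fell by 1.89, SE 0.35), followed. The probe that represented EGR3 did not pass at 1.54 (SE 0.45, adjusted p = 0.0623). Its log2 signal was 6.81 ± 0.66 (SD, n = 2) with Ad-EGR3, 5.27 ± 0.67 (SD, n = 2) with Ad-GFP and 6.35 ± 0.35 (SD, n = 4) in untreated cells, and Ad-EGR3 was not tested against untreated cells. The place of that probe relative to the transgene was not analysed here.

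Of 33 genes of the TGF-beta response and myofibroblasts, 3 rose with Ad-EGR3 and none fell: IL11, a profibrotic cytokine (2.93, SE 0.76), ID1, a target of BMP signalling (2.09, SE 0.54) and CDH2, N-cadherin (0.82, SE 0.22). Adjusted over the list alone, 14 rose and 1 fell, and camera called the list higher (adjusted p = 7.68e-05), with adjusted p = 0.231 with an estimated correlation. ACTA2 was at 0.90 (SE 0.27, adjusted p = 0.0732) and COL1A1 at -0.07 (SE 0.18, adjusted p = 0.877). Of 12 fibroblast identity genes 1 fell, PDGFRA, a growth factor receptor (fell by 1.27, SE 0.34), and 6 fell adjusted over the list alone (adjusted p = 0.00465; adjusted p = 0.231 with an estimated correlation). Of 7 leukocyte markers CD52 was at least 6.84-fold higher, and 4 rose adjusted over the list alone (adjusted p = 0.0135; adjusted p = 0.557 with an estimated correlation; adjusted p = 0.192 with no filter on detection). Of 30 chemokines and cytokines, CX3CL1 (at least 10.8-fold) and CXCL16 (1.86, SE 0.46) rose and CSF1, a macrophage growth factor, was at least 2.04-fold lower, with the list not called (adjusted p = 0.384). Of 38 matrix genes COL5A3 (2.16, SE 0.46) and PLOD2, a collagen lysyl hydroxylase (0.80, SE 0.20), rose and LOXL1 fell by 0.81 (SE 0.20). Of 18 proteases and inhibitors MMP2 fell by 1.07 (SE 0.23). In smooth muscle markers DES, desmin (4.04, SE 0.77), and NOTCH3 (1.40, SE 0.33) rose and LMOD1 fell by 1.27 (SE 0.34), with the list not called (adjusted p = 0.155). None of 36 interferon-stimulated genes passed (adjusted p = 0.155), and the median of the list was -0.50. The 3 called lists moved mostly on Ad-EGR3 b. Relative to the mean of the controls, the TGF-beta list stood at 0.05 on Ad-EGR3 a and 0.74 on b, against -0.24 and -0.22 on Ad-GFP a and b. Fibroblast identity stood at -0.105 and -0.768, against 0.317 and -0.002. Leukocyte markers stood at 0.163 and 1.9, against -0.406 and 0.301.

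In all, 521 genes were called for Ad-EGR3 against Ad-GFP, 282 higher and 239 lower, with a median log2 difference of all genes of -0.23 under median scaling against -0.05. The count was 280 without Ad-GFP a, 1516 without Ad-GFP b, 3935 without Ad-EGR3 a and 70 without Ad-EGR3 b, each leaving a lone array assumed to vary like the other groups. The 10 named genes with the strongest increases passed in all of these. In contrast, 35.7% of the called named genes passed without Ad-EGR3 b, 47.6% without Ad-GFP a, 83.3% without Ad-GFP b and 97.6% without Ad-EGR3 a. IL11, ID1, CDH2 and PDGFRA missed without Ad-GFP a or Ad-EGR3 b (adjusted p = 0.155 to 0.587). With only these 4 arrays in the fit, 0 genes were called in limma and 399 had an unadjusted p under 0.05.

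Ad-GFP against untreated cells called 0 genes in limma, with 1585 at an unadjusted p under 0.05. Infection and the 48 h in culture cannot be told apart in this comparison. The interferon-stimulated list was higher by camera (median log2 fold change 1.54, adjusted p = 7.81e-13), but adjusted p = 0.369 with an estimated correlation. LGALS3BP, a secreted glycoprotein, was at 1.56 (SE 0.32, n = 2 against 4, adjusted p = 0.0916), HLA-F at 1.67 (SE 0.32, adjusted p = 0.0818), and CSF1 at 1.06 (SE 0.23, adjusted p = 0.0916). MVD, an enzyme of the mevalonate pathway, was at 1.14 (SE 0.24, adjusted p = 0.0916) and PHLDA3, a p53 target, at 1.02 (SE 0.22, adjusted p = 0.0916). Chemokines and MHC class I antigen presentation (both adjusted p = 2.5e-06), sterol synthesis (adjusted p = 2.52e-05), and p53 targets (adjusted p = 0.000146) were also called higher. So were NF-kB genes (adjusted p = 0.00942), NRF2 targets (adjusted p = 0.0104), the unfolded protein response (adjusted p = 0.0125) and RNA sensing (adjusted p = 0.0205), and the TGF-beta response was called lower (adjusted p = 0.0202). None of these 10 calls held with an estimated correlation (adjusted p = 0.303 or more). Adjusted over the list alone 7 of 16 MHC class I and 6 of 18 sterol synthesis genes passed. Relative to the mean of the controls the interferon-stimulated list stood at 1.35 on Ad-GFP a and 1.91 on Ad-GFP b, against 1.83 on untreated control a and -0.65, -0.62 and -0.55 on controls b, c and d. The count of 0 became 580 without Ad-GFP b, 5 without Ad-GFP a (each leaving a lone Ad-GFP array) and 3 without control d. With median scaling the median log2 fold change of all genes was 0.11 against 0.00.

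Neither HSP60 nor HMGB1 gave a called gene in limma against untreated cells, with 360 and 852 genes at an unadjusted p under 0.05. The count with HSP60 lies below the 723 that chance would give, so its lack of calls says little. With HSP60, EDN1 was at -1.32 (SE 0.57, n = 2 against 4, adjusted p = 1). ABCC9, a potassium channel subunit, was at a fold of at least 1.7 and LAPTM5, a lysosomal protein of leukocytes, at least 1.35, both also at adjusted p = 1. HSPD1, the gene of HSP60, was at 0.13 (SE 0.20, adjusted p = 1). With HMGB1, POSTN, the matrix protein periostin, was at -2.13 (SE 0.57, n = 2 against 4, adjusted p = 0.807), MVD at 0.98 (SE 0.24, adjusted p = 0.793) and the HMGB1 transcript at -1.03 (SE 0.26, adjusted p = 0.807). Camera called interferon-stimulated genes higher with both (adjusted p = 0.000199 with HSP60 and 9.59e-05 with HMGB1). With an estimated correlation these were adjusted p = 0.842 and 0.663. The list mean stood at -0.58 on HSP60 4 and -0.69 on HMGB1 4, below the mean of the controls, and at 1.99 on HSP60 5 and 2.24 on HMGB1 5. Chemokines and cytokines stood at -0.55 and -0.65 on the arrays numbered 4 and at 1.80 and 1.79 on those numbered 5. With HSP60 camera also called p53 targets (adjusted p = 0.00028), sterol synthesis (adjusted p = 0.0097), chemokines and the unfolded protein response (both adjusted p = 0.0151) higher. With HMGB1 it called sterol synthesis (adjusted p = 0.000272), NRF2 targets (adjusted p = 0.00404), p53 targets (adjusted p = 0.00783) and MHC class I (adjusted p = 0.0193) higher and the TGF-beta response lower (adjusted p = 0.026). None of these held with an estimated correlation (adjusted p = 0.394 or more with HSP60 and 0.53 or more with HMGB1), and of the sterol genes 3 of 18 passed with HMGB1 adjusted over the list alone. With control a, Ad-GFP b, HSP60 5 and HMGB1 5 left out together, an alternative chosen after the data were seen, each treatment was a lone array (HSP60 4 or HMGB1 4) tested with the spread of other groups. None of the lists called here then passed, which with 1 array does not show that the treatments left them unchanged. For interferon-stimulated genes the adjusted p was 0.957 with HSP60 and 0.579, with the direction turned to lower, with HMGB1.

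The direct comparison of HSP60 with HMGB1 also called 0 genes in limma, with 278 at an unadjusted p under 0.05, and no list. Chance alone would give 723 such genes. HSP60 5 correlated with HMGB1 5 at 0.9925 and with HSP60 4 at 0.9672. The difference between arrays numbered 4 and 5 enters the spread of this unpaired test. The absence of calls therefore does not show that the treatments act alike. POSTN was at 1.25 (SE 0.66, adjusted p = 1) and HMGB1 at 0.76 (SE 0.30, adjusted p = 1). With median scaling the median log2 difference of all genes was 0.23 against 0.02, and that of HMGB1 against control was -0.18 against -0.01. Without HMGB1 5, which leaves a lone HMGB1 array, the count for HMGB1 against control was 1.

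The single array of CDDO, a synthetic triterpenoid, showed high levels of antioxidant genes. HMOX1, heme oxygenase, was at a log2 signal of 12.8 against 9.56 ± 0.22 (SD, n = 4) in untreated cells. SRXN1, sulfiredoxin, was higher by 2.64 log2 units, GCLM, of glutathione synthesis, by 2.20, the transporter gene ABCC3 by 2.46, PIR by 2.42 and NQO1, a quinone reductase, by 1.80. NMRAL2P, a pseudogene, was higher by 3.32, ANGPTL4, an inhibitor of lipoprotein lipase, by 2.76, HBA2 by 2.69 and PANX2 by 2.53. TREML3P, a pseudogene, and AKR1B10, an aldo-keto reductase, were at least 9.54-fold and 4.01-fold higher. Lower were CXCL8 (-3.68) and CXCL1 (-3.38), both neutrophil chemokines that spread widely between the controls (SD 2.48 and 2.20). So were DHRS3, a retinaldehyde reductase (-3.61), MEDAG (-2.94), EDN1 (-2.74), the secreted matricellular gene CCN3 (-2.65) and the prostacyclin synthase gene PTGIS (-2.52). TGM2, a transglutaminase, VCAM1, an adhesion molecule, and NPTX1 were at least 8.46-fold, 5.4-fold and 4.74-fold lower. EGR3 was at -1.37 and COL1A1 at -0.15. The median of 22 NRF2 targets was 1.41, at percentile 100 of the random lists, and 15 of them were at least 1 log2 unit higher. Sterol synthesis (median 0.46, percentile 100) and p53 targets (median 0.334, percentile 99.96) were also high. NF-kB genes (median -0.696), interferon-stimulated genes (median -0.602), the cell cycle (median -0.524), the TGF-beta response (median -0.364) and chemokines (median -0.308) were at percentile 0. The random lists ignore that members of a list can move together. Even leukocyte and smooth muscle markers were at percentiles 0.95 and 0.7, so an extreme percentile alone shows little.

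In all, 360 genes lay at least 1 log2 unit from the control mean and outside the control range with CDDO, 152 higher and 208 lower. The same rule gave 140, 43, 47 and 61 for controls a, b, c and d. With CDDO 91 of the higher and 90 of the lower lay outside all 21 other arrays. With median scaling 218 were higher and 172 lower. The interferon-stimulated list of this array stood at -0.71 relative to the mean of the controls, where control a stood at 1.83 and the other 3 controls at -0.65 to -0.55. Chemokines stood at -0.69, against 0.85 on control a and -0.39, -0.51 and 0.05 on controls b, c and d, and NF-kB genes at -0.77, against 0.99 and -0.49, -0.45 and -0.05. Control a therefore makes up part of the low percentiles of these 3 lists, which do not by themselves show an effect of CDDO. With 1 array the spread of CDDO-treated cells is unknown.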

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

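The tests of the 3 patterns weighed here and the counts of other splits of the arrays were chosen or written down after the results they measure had been seen.

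Among the 4 untreated arrays, control a stood far from the other 3 in antiviral genes. The gap of its interferon-stimulated list to the nearest control took up 0.96 of the range of the 4 controls, and that of RNA sensing 0.93, both above the 95% critical value of Dixon's test. Control d was lowest in extracellular matrix (0.83). These were 3 of 22 lists, and chance passes about 1 in 20, or 1.1 lists. None of 6 measures of array quality passed among these 4 controls, and the treated arrays were not tested in this way. Of 291 named genes 36 passed, where chance gives 14.6, and control a was the highest array in 21 of them. These were MX2 (1), OAS1 (0.95), OAS2 (0.93), SAMD9 (0.93), CXCL10 (0.92), IFIT3 (0.91), EDN1 (0.91), TNIP1 (0.91), IFI44L (0.9), IFI27 (0.89), TAP2 (0.88), BST2 (0.88), IFIT2 (0.86), MYD88 (0.86), HERC5 (0.86), CXCL16 (0.85), EPSTI1 (0.85), CXCL5 (0.85), RSAD2 (0.84), CSF1 (0.84) and HLA-B (0.83). Control a was lowest for FABP3 (0.9) and EGR1 (0.88). Control b was highest for CXCL9 (0.99), CXCL11 (0.92) and PGD (0.87) and lowest for BBC3 (0.88) and KRT10 (0.85). Control c was highest for DHCR7 (0.92), HSPB1 (0.86) and DUSP5 (0.83) and lowest for PCTP (0.9) and CASP1 (0.84), and control d was highest for CCNB2 (0.87) and lowest for COL1A2 (0.89) and COL7A1 (0.84).

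The first pattern is that interferon-stimulated genes and chemokines were higher on control a, HSP60 5, HMGB1 5 and Ad-GFP b than on the other arrays of their groups. For Ad-GFP the gap between b and a was smaller (1.91 against 1.35 in interferon-stimulated genes, 1.79 against 0.95 in chemokines). Ad-EGR3 b also stood above a in chemokines (1.76 against -0.24) but not in interferon-stimulated genes (1.06 against 1.1). The tables argue against RNA of poly(I:C) 24 h cells mixed in, since 52.2% of 452 values lay more than 1 log2 unit from the level such a mixture gives. These values come from 241 genes, each counted on every one of the 4 arrays where the mixture would raise it. The tables also argue against mislabelled IFN-beta or poly(I:C) arrays. The highest mean of the 4 arrays was 2.24, and the lowest IFN-beta array stood at 3.88. Control a was untreated and stood at 1.83, so the HSP60, HMGB1 or virus treatments cannot be the cause there. Control a is part of how the pattern was chosen, so this does not decide the cause on HSP60 5, HMGB1 5 or Ad-GFP b. RNA of IFN-beta cells as the whole cause of the chemokines is argued against on HSP60 5, HMGB1 5 and Ad-GFP b. There 8, 9 and 10 of 30 chemokines and cytokines lay more than 1 log2 unit above both the highest IFN-beta array and the highest of controls b to d, and a mixture at any share cannot exceed both. The list means of these arrays were 1.80, 1.79 and 1.79, against 1.51, 1.64 and 0.34 on the IFN-beta arrays. For the chemokines on control a, 0 of 30 lay above that level. However, 3 of the 7 that a mixture at the median share would raise lay more than 1 log2 unit from its level. There the same explanation stays open. It also stays open for the genes IFN-beta raises most, as 17.4% of 224 values (56 genes on 4 arrays) lay more than 1 log2 unit from the level a mixture gives. Medium carried over from IFN-beta cells was not tested. A shared culture or processing day could also matter. Across genes, the HSP60 5 minus 4 difference correlated with that of HMGB1 at r = 0.536 and with Ad-GFP b minus a at r = 0.554. The other 4 pairs of these differences, with control a minus b as the fourth, correlated at only 0.159 to 0.316. These arrays were chosen for genes raised on them, and those genes stayed in the correlations. Positive values therefore follow in part from that choice and do not argue for a shared day. The labels name no day, and a shared day was not tested.

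The second pattern is that Ad-EGR3 a changed less than Ad-EGR3 b, at a slope of 0.32 over the called genes (r = 0.86 across genes, which are not independent replicates). For a smaller infected share as the whole cause, the change on a was set over that on b on the linear scale. The median was 0.35 for 101 genes called lower and 0.083 (quartiles 0.043 to 0.12) for 158 called higher, where a single share would give a single ratio. Changes were taken from untreated cells, so effects of the virus that a and b share enter these ratios. The genes were also chosen by unequal cutoffs on b. Whether these choices make the ratios unequal was not tested, so the explanation is not decided. A difference between arrays lettered a and b that Ad-GFP shares cannot be told apart. Over the 153 genes called higher and detected on all 4 virus arrays, the median b minus a difference was 0.16 with Ad-GFP (quartiles -0.23 to 0.57) and 1.16 with Ad-EGR3 (0.49 to 2.03), so the quartiles overlapped. Over the 206 such genes called lower, the median difference in the direction of the call was 0.24 (-0.05 to 0.56) and 0.66 (0.35 to 1.08). The remaining called genes lay at background on at least 1 of these arrays and decide nothing. A different level of EGR3 protein per cell may remain as well, and was not tested.

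The third pattern is the low count at 2 h of poly(I:C), 45 genes. Spread between the 4 virus arrays, which share the fit, is a candidate explanation: without them 493 genes were called, 212 higher and 281 lower, the same 45 among them, and the median standard error was 0.181 against 0.223. The median SD between arrays was 0.309 for Ad-GFP and 0.354 for Ad-EGR3 against 0.19 for the controls. A biological explanation, the short time itself, stays open and was not tested apart.

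The change from control differed between 2 h and 24 h of poly(I:C) for 4933 genes by the direct test of the times. Among the genes named at 2 h, the 24 h minus 2 h log2 difference was -1.56 for IFNB1, 2.54 for IFIT2, -2.09 for ANKRD36BP1, 6.53 for OASL, -0.78 for ZFP36, 1.57 for NPIPA1, 0.70 for GOLGA8B, 1.44 for PCTP, 1.38 for SMG1P1, 1 for FAM133CP, 1.43 for AKAP10 and 0.85 for NBPF14. The lists that differed by camera were interferon-stimulated genes (adjusted p = 4.67e-22), RNA sensing (1.66e-07), MHC class I antigen presentation (3.48e-14), chemokines and cytokines (2.35e-11), NF-kB genes (8.92e-05), the cell cycle (0.0131) and cell death (1.1e-07). With an estimated correlation only MHC class I antigen presentation and cell death held (both 0.0279). The others were lost, at 0.225 for interferon-stimulated genes, 0.119 for RNA sensing, 0.225 for chemokines and cytokines, 0.566 for NF-kB genes and 0.702 for the cell cycle.

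The arrays of each comparison of groups of 3 or more were also split in every other way of the same sizes. For the genes called, only the real split, 1 of 35, reached its count in the comparisons of these groups with control. The counts were 45 at 2 h (highest other 0), 5100 at 24 h of poly(I:C) (highest other 2537) and 309 with IFN-beta (highest other 146). The highest other split of the latter pair set controls b, c and d against the rest. The other splits mix treated and untreated arrays within a group, which widens the spread and lowers their counts. Chance is therefore made less likely and not excluded. For the lists called, chance cannot be excluded: 7 of 35 splits gave as many as the 6 at 2 h (highest other 7), 12 of 35 as many as the 7 at 24 h (highest other 8) and 12 of 35 as many as the 7 with IFN-beta (highest other 12). For poly(I:C) 24 h against 2 h and against IFN-beta the 10 splits are too few for a share under 0.05. The real counts there were 4933 and 3370 genes with a highest other of 0 in each, and 7 and 8 lists (reached by 5 and 4 splits) with a highest other of 7 and 10. The 3 other splits that part every pair of the 2 h and 24 h arrays called 0 genes.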

How the results depend on the processing

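Leaving out control a, Ad-GFP b, HSP60 5 and HMGB1 5 together, and control a alone in the list tests, were alternatives chosen after seeing the data. The others were planned, and the array chip as a block was not run because the deposited files name no chip. Where an array of a group of 2 is left out, that group is a lone array tested with the spread of the other groups, so its counts and list calls say little about that treatment. Counts of genes that moved by over 1.5 times are given here, and their cause was not tested unless stated.

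For poly(I:C) at 2 h, 45 genes became 90 with the authors' values (36 higher), 92 without background correction, 11 with median scaling, 511 with only the 2 groups in the fit, 1198 with array weights, 26 with a log2 fold change of at least 1, and 6 to 23 without 1 array. A minimum log2 fold change of 1 left 2735 genes at 24 h, 2872 for 24 h against 2 h and 1780 for poly(I:C) against IFN-beta, by its construction. IFN-beta went from 309 to 1095 with only the 2 groups, 1610 with array weights and 180 to 288 without 1 array. Poly(I:C) against IFN-beta went from 3370 to 5579 with only the 2 groups and 5842 with array weights. Ad-EGR3 against Ad-GFP went from 521 to 0 with only the 2 groups (399 genes at an unadjusted p under 0.05 in limma), 28 with array weights, 70 to 3935 without 1 array and 1593 without the 4 arrays that stand apart. Ad-GFP against control went from 0 to 23 with the authors' values and 23 without background correction, 2 with only the 2 groups, 7 with trend and robust moderation, 614 without the 4 arrays and 0 to 580 without 1 array. HMGB1 went from 0 to 2 with only the 2 groups, 13 without the 4 arrays and 0 to 1 without 1 array, and HSP60 against HMGB1, then 1 array against 1, from 0 to 4 without the 4 arrays. HSP60 against control stayed at 0 in every setting run. CDDO went from 360 to 132 with the authors' values and 131 without background correction. Without the 4 arrays the counts at 2 h, 24 h and with IFN-beta were 45 (30 of them shared), 5424 and 436.

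With the replicate letter or number as a block, 1291 genes were called at 2 h, 1016 with IFN-beta, 5943 for poly(I:C) against IFN-beta, 7163 for poly(I:C) 24 h against 2 h and 0 for Ad-EGR3 against Ad-GFP (876 at an unadjusted p under 0.05 in limma). These fits, and the list tests with the block, also left arrays out. They kept only the control, poly(I:C) and IFN-beta arrays, or only the 2 groups compared where these were virus arrays or HSP60 and HMGB1. Leaving arrays out without a block moved the counts too, so these counts do not measure the block alone. For Ad-EGR3 against Ad-GFP, the fit of only the 2 groups without a block also called 0 genes. For poly(I:C) 24 h against 2 h, where the letters pair the samples, the block ended no list call. Elsewhere the samples share only a letter or number. Same-lettered deviations correlated above 0.1 in 0 of 3 pairs for control with poly(I:C) 2 h, and in 2 of 3 pairs for control with poly(I:C) 24 h, control with IFN-beta and poly(I:C) 24 h with IFN-beta. The correlation was 0.291 for the 2 pairs of Ad-GFP and Ad-EGR3 and 0.536 for those of HSP60 and HMGB1, and -0.202 and -0.098 for control with Ad-GFP. Among the groups of 3 or more named here, each sample correlated best with its own letter for control with poly(I:C) 24 h only, and between 2 groups of 2 arrays any positive correlation gives this by construction.

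Of 59 list calls, 9 held with an estimated correlation, 53 with median scaling and 55 with no filter on detection. The block kept 45 of 48, leaving out control a 39 of 41, and leaving out the 4 arrays 26 of 44. In the last setting 4 lists turned direction, all without passing: with HSP60 chemokines and cytokines (adjusted p = 0.16), sterol synthesis (adjusted p = 0.16) and the unfolded protein response (adjusted p = 0.957) and with HMGB1 interferon-stimulated genes (adjusted p = 0.579). Leaving out control a also added list calls, 51 in all against 41 in the same comparisons. The lists called against control went from 5 to 11 with HSP60 and from 6 to 10 with HMGB1. With the block, Ad-EGR3 against Ad-GFP went from 3 to 7 lists. Median scaling took poly(I:C) at 2 h from 6 to 2 lists. Of 379 calls of named genes, none turned direction in any setting, and 337 to 373 were kept in the settings that tested them again in full. Without 1 array 35.7 to 97.6% of those in the comparisons touched were kept. The correlation of the poly(I:C) and IFN-beta responses was 0.634 with separate controls and 0.657 to 0.734 in the other settings that use all arrays. Genes near background limit these results: 38.8 to 44.4% of probes were detected on each array.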

Other observations

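The fit without the 4 virus arrays was chosen after the results were seen. In this setting, described above as giving 493 calls at 2 h of poly(I:C), several genes that had missed with all arrays passed. TNF was at least 2.05-fold higher (adjusted p = 0.000477), and PTGS2, the inducible cyclooxygenase, was at a log2 fold change of 2.24 (adjusted p = 0.0451), JUNB at 1.30 (adjusted p = 0.0198) and TICAM1, the adaptor of TLR3, at 1.06 (adjusted p = 0.0027). In this fit 4 of 19 NF-kB genes and 4 of 23 immediate early genes were higher and none of either list lower, 1 of 30 chemokines and cytokines was higher, and 2 of 18 proteases and inhibitors were lower, MMP2 at -0.72 (adjusted p = 0.0114) and MMP14 at -0.81 (adjusted p = 0.0306). DDIT3, a stress transcription factor, was at -0.83 (adjusted p = 0.022), MCL1, an anti-apoptotic protein, at -0.69 (adjusted p = 0.0201) and TXNRD1, thioredoxin reductase, at -0.71 (adjusted p = 0.024). EGR1 (0.29, adjusted p = 0.498), EGR3 (0.15, adjusted p = 0.846), IL6 (2.54, adjusted p = 0.246) and NFKBIA, the inhibitor of NF-kB (1.39, adjusted p = 0.0997), did not pass. The same fit called 6413 genes at 24 h of poly(I:C), 657 with IFN-beta, 6286 for 24 h against 2 h, 4847 for poly(I:C) against IFN-beta, and 0 in limma for HSP60, HMGB1 and their comparison.

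Of the 2 detected EGR3 probes, the one of weaker signal did not fall at 24 h of poly(I:C) (log2 fold change 0.215). By the stronger, which represented the gene, the EGR3 transcript was called lower (at least 2.35-fold). Its log2 fold change was 0.15 at 2 h of poly(I:C), -1.05 with IFN-beta (adjusted p = 0.167), -1.08 with Ad-GFP (SE 0.39, adjusted p = 0.278), -1.06 with HMGB1 (SE 0.39, adjusted p = 0.807), -0.63 with HSP60 (SE 0.39, adjusted p = 1) and -1.37 on the CDDO array, none of which passed or could be tested. All of these values share the same 4 controls, so a control mean that is high by chance would lower every one of them. The direct test of 24 h against 2 h of poly(I:C) uses no controls, and the probe that represented EGR3 was called lower there (-2.10). That argues against a high control mean as the whole cause of the fall at 24 h of poly(I:C). For the other treatments a high control mean was not tested. HBA2 was high with Ad-EGR3 against Ad-GFP (5.67, SE 0.79) and on the CDDO array (2.69), and EDN1 was low on the CDDO array (-2.74) and high at 24 h of poly(I:C) (2.92, SE 0.51). Whether the HBA2 and EDN1 values differ between these treatments was not tested.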
